A study of Danio rerio with 16 samples.

How the data were processed

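RNA sequencing was used to measure gene expression in adult zebrafish hearts. Per the labels, hearts came from wild-type fish and from tert hu3430 mutants aged 6 to 9 months, without injury or 3 days after cryoinjury. Each of the 16 libraries was made from polyadenylated RNA of 3 pooled hearts with the TruSeq RNA v2 kit, and the labels call the 4 libraries of each group biological replicates. Groups were taken from the sample titles.

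The deposited table holds 1 column per library and 14500 genes named by Ensembl identifier. Its values are a normalized signal made by the authors before deposit, and the scaling is not given in the sources used here. The submitters' processing notes name CASAVA 1.8.2, cutadapt, RSEM 1.2.3 and the genome build Zv9, without saying what each was used for. In every column 100% of values were whole multiples of a single step, within 0.01 read, so the signal was read counts scaled by 1 factor per library. A read was worth 0.06 to 0.1961 units, and column totals ranged from 865174 to 1168450 units. Dividing by the step gave 5611576 to 14831664 reads per library over the listed genes. The shallowest libraries were in the KO groups, with 5611576 reads in KO cryoinjury library 3, 5762597 in KO control library 4 and 5842366 in KO cryoinjury library 1. Low genes had been left out before deposit, since the 4th highest library of every gene held at least 1.76 units. Low genes rest on few reads, so a difference in them was less detectable, most of all in these libraries. The 10 most abundant genes took 21.5 to 23.5% of the reads in control hearts and 15.3 to 18% after injury, so changes depend on the scaling between libraries. The authors' scaling was kept, and rescaling the recovered reads with DESeq2's size factors moved the median change of all genes by 0 in every contrast.

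Symbols were taken from a reference table of gene names, which matched 11702 of the 14500 identifiers, and 1219 identifiers shared a symbol with another, in which case the identifier is given. The other 2798 kept their identifier. Which genes share a chromosome was taken from the RefSeq genes of assembly GRCz12tu, and no coordinates were used, since the build differs from that of the table. Reads of close gene copies may have been split by the authors' counting, and the kit does not mark strand, so overlapping antisense genes cannot be told apart.

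The test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(value + 1), in a model of the 4 group means over all 16 libraries, with 12 residual and 5.12 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The p-values were adjusted by the Benjamini-Hochberg method over 14500 genes, and an adjusted p under 0.05 counted as past the threshold. The design set down before the data were examined named edgeR's quasi-likelihood test for counts and limma for normalized values, so limma was used. It fixed 5 contrasts: injury in WT, injury in KO, genotype in control hearts, genotype in injured hearts, and the interaction. It also fixed the 25 gene lists, the alternatives other than those named as added, and the rule for naming genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists within a contrast, and again with the correlation estimated from the data. Of 1336 list names, 776 were matched, from 13.6% of the lymphocyte list upward. List scores were the mean log2(value + 1) of the members in a library, and their interaction was tested by exact 2-sided permutation of genotype within injury status. That test is exact only if genotype has no effect in either status, so it does not isolate the interaction. With 4 against 4 libraries there are 70 arrangements, and the smallest 2-sided exact p is 0.0286.

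The rule for named genes took tert, then for each pairwise contrast the 10 highest and 10 lowest log2 changes. These were taken among genes past the threshold, with a mean above the median gene, no overlap between the groups' libraries and a symbol that was not a placeholder. From each list and contrast it took up to 4 members with the smallest p. Some genes the rule took are not reported here. The lists of skin and epithelial, clock, and glucocorticoid or fasting genes were added after the data were seen. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 6.7 to 18.8 between libraries of a group, so no library was a copy of another.

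Alternatives were other size factors (DESeq2's median of ratios), library totals with no composition correction, a higher filter on low genes, limma voom, the DESeq2 1.42.0 Wald test, fits of only the 8 libraries compared, a replicate block, thinning to the smallest library, pseudocounts of 0.5 and 10, a threshold of 0.01, and leaving out each library. The edgeR 4.0.16 quasi-likelihood test on the recovered reads, and a fit without KO cryoinjury libraries 1 and 2, were added after the data were seen. That edgeR test called 3517 genes higher and 3224 lower in WT injury, 3570 and 3193 in KO injury, 51 and 125 between genotypes in control hearts, 55 and 29 in injured hearts, and 0 for the interaction.

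The limma steps were tested on simulated reads for 14500 genes. Reads were drawn from the WT control means in every group, with the real library sizes. In each contrast 67, 67 and 66 genes were changed 1.5, 2 and 4-fold, and all others were left unchanged. At these folds 22.4, 80.6 and 97% were recovered for WT injury and 34.3, 71.6 and 97% for KO injury. For the genotype difference 43.3, 74.6 and 95.5% were recovered in control hearts and 29.9, 73.1 and 95.5% in injured hearts, and for the interaction 6, 47.8 and 77.3%. The false share of calls was 6.3, 6.9, 7.2, 2.2 and 3.3% in these contrasts. In the real injury contrasts 45.9% (WT) and 47.6% (KO) of genes passed, so the simulated shares need not hold there. A shift in composition between groups was not simulated. Figures were drawn with matplotlib 3.10.9.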

Results

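Hearts of adult zebrafish aged 6 to 9 months were profiled by RNA sequencing in wild-type (WT) animals and in mutants of tert, the gene for the catalytic subunit of telomerase (allele hu3430, called KO here after the labels). Hearts were taken without injury or 3 days after cryoinjury, in which part of the ventricle is killed by a cold probe. The 4 groups, WT control, WT cryoinjury, KO control and KO cryoinjury, held 4 libraries each, and every library was made from a pool of 3 hearts. Values were given for 14500 genes, and the reads recovered for these genes ranged from 5611576 in KO cryoinjury library 3 to 14831664 in WT cryoinjury library 4. The study title and design text set the question: how the heart transcriptome responds to injury with and without telomerase.

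Injury status was the main difference between libraries. The first principal component of the 500 most variable genes held 74.7% of the variance and had the 8 control libraries at -29.16 to -19.13 and the 8 cryoinjury libraries at 20.09 to 33.44. The second component, with 6.5% of the variance, placed KO cryoinjury libraries 1 and 2 at -14.23 and -17.69, while libraries 3 and 4 of that group lay at 3.00 and -2.40. These libraries also differed in the skin and epithelial keratin gene krt5, which read 337, 887, 12 and 75.4 in KO cryoinjury libraries 1 to 4 and between 4.68 and 67.4 in the other 12 libraries. The krt5 gene was chosen after its values were seen. Within groups, Pearson correlations of log2 values across genes, which are not independent replicates, were 0.968 to 0.984.

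**Figure D1:**
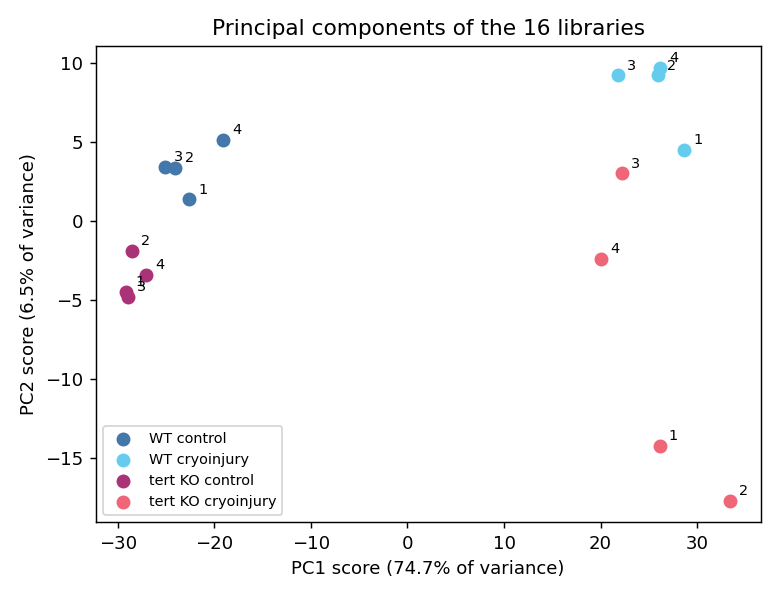
Scores of the 16 libraries on the first component (horizontal axis, 74.7% of variance) and the second component (vertical axis, 6.5% of variance) of the 500 most variable genes; each point is a library, coloured by group and numbered by replicate. Control and cryoinjury libraries lie apart on the first component, and KO cryoinjury libraries 1 and 2 have the lowest second scores, -14.23 and -17.69.

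The tert transcript itself was more abundant in KO than in WT libraries. In deposited normalized units it read 1.24, 1.19, 1.42 and 1.97 in WT control libraries 1 to 4, and 1.99, 2.83, 2.85 and 5.16 in WT cryoinjury. It read 6.45, 5.65, 6.56 and 5.69 in KO control libraries 1 to 4, and 6.25, 6.79, 6.84 and 6.46 in KO cryoinjury. All 8 KO libraries lay above all 8 WT libraries. The group means ± SD (n = 4) were 1.45 ± 0.357, 3.21 ± 1.36, 6.09 ± 0.484 and 6.59 ± 0.281. In control hearts KO exceeded WT by 1.54 on the log2(value + 1) scale (SE 0.18, limma adjusted p = 0.000327), and after cryoinjury by 0.90 (SE 0.18, limma adjusted p = 0.0365). In WT hearts tert rose by 0.74 after cryoinjury (SE 0.18, limma adjusted p = 0.00268), and in KO hearts the difference was 0.10 (limma adjusted p = 0.674). The difference between these responses did not pass (interaction -0.64, SE 0.25, limma adjusted p = 0.55). The WT libraries held 7 to 86 tert reads and the KO libraries 29 to 58. As background, hu3430 is a point mutation that creates an early stop codon, so reads from the rest of the transcript are still counted and their level does not test whether the protein is lost. The call in injured hearts ended with the 8 injured libraries alone in the fit (0.90, limma adjusted p = 0.115), without KO cryoinjury libraries 1 and 2 (0.91, limma adjusted p = 0.169) and in edgeR on recovered reads (0.99, adjusted p = 0.0529). It also ended without any single cryoinjury library except WT cryoinjury library 4 (limma adjusted p up to 0.113, without WT cryoinjury library 2).

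**Figure D2:**
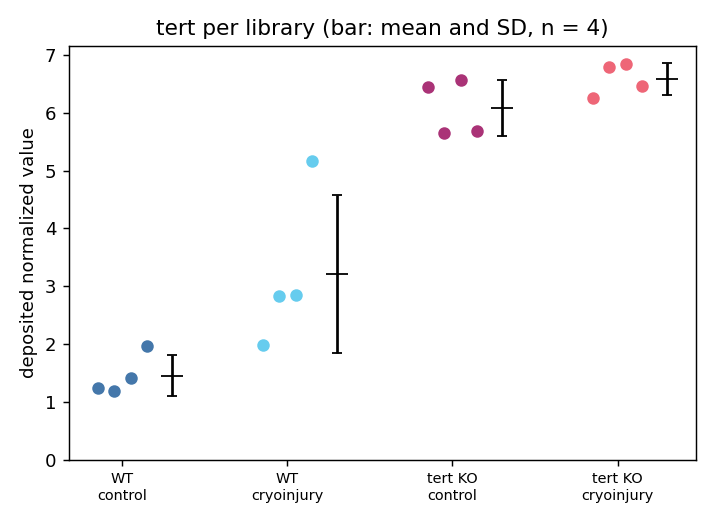
Deposited normalized value of tert (vertical axis) in each library of the 4 groups (horizontal axis); points are libraries, and the cross and bar are the mean and SD of 4 libraries. All 8 KO libraries, from 5.65 to 6.84, lie above all 8 WT libraries, from 1.19 to 5.16.

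In WT hearts, cryoinjury raised genes of the extracellular matrix, of immune cells and of cell division, and lowered genes of mitochondrial metabolism and of cardiac muscle. The collagen XII gene col12a1 (ENSDARG00000019601) went from 3.55 ± 2.44 to 203 ± 43.8 (SD, n = 4; log2 change 5.66, SE 0.32). The fibronectin gene fn1 (ENSDARG00000019815), a component of the provisional matrix, went from 52.4 ± 14.7 to 1330 ± 240 (4.67, SE 0.21). The granulin gene grna.1 rose from 4.06 ± 1.19 to 250 ± 83.8 (5.61, SE 0.36). Among the genes that fell, the homeobox gene irx2 went from 42.7 ± 15.4 to 5.61 ± 1.52 (-2.69, SE 0.21) and the muscle ubiquitin ligase gene fbxo32 from 30.5 ± 4.08 to 5.39 ± 0.808 (-2.30, SE 0.20). These 5 genes had limma adjusted p of at most 1.05e-07.

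With limma, 3506 genes were higher and 3149 lower in WT cryoinjury than in WT control at an adjusted p under 0.05, and 1367 of the higher and 403 of the lower genes changed by over 2-fold. Other genes among the largest rises were grna.2 (5.1), the thioredoxin gene txnb (4.71), the tetraspanin gene cd9b (4.61), the cardiac stress gene ankrd1 (4.36), adamtsl7 (4.11) and the apolipoprotein E gene apoeb (3.95). The other largest falls were in the pancreatic protease gene ctrb.1 (-2.78), the glycogen phosphorylase gene pygl (-2.06), mtus1a (-2), gpr22 (-1.99), itih3a.2 (-1.91), arhgef9a (-1.90), the muscle ubiquitin ligase gene trim63b (-1.89) and the gap junction gene gja3 (-1.88). The pygl call, at a limma adjusted p of 0.0405, was lost in edgeR on recovered reads (adjusted p = 0.0513), in DESeq2 (adjusted p = 0.0975), with no composition correction (-1.74, adjusted p = 0.0704) and without single libraries, up to 0.158 without WT cryoinjury library 2, where the change was -1.33. Scaling to library totals alone, with no composition correction, moved the median change of all genes by 0.33 and the lower share of called genes from 47.3% to 15.8%, so all directions here are relative to the composition-corrected scale.

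Of 73 measured genes of DNA replication and mitosis, 69 rose and none fell in WT hearts, both over all genes and adjusted over the list alone. The median change was 2.04 (camera adjusted p = 8.42e-28; adjusted p = 0.0937 with an estimated correlation). The cyclin B1 gene ccnb1 rose from 1.27 ± 0.415 to 18.3 ± 2.38 and the proliferation marker gene mki67 from 6.33 ± 2.47 to 50.2 ± 8.20 (limma adjusted p = 8.67e-10 and 5.23e-09). Nucleolar and ribosome assembly genes moved less, with a median of 0.32 (camera adjusted p = 6.77e-05; adjusted p = 0.28 with an estimated correlation). Of 53 such genes 29 rose and 1 fell (30 and 1 adjusted over the list alone), among them npm1a, from 80.8 ± 18.7 to 155 ± 7.50. Of 18 telomerase and telomere maintenance genes, 9 rose and none fell, also adjusted over the list alone (median 0.30, camera adjusted p = 0.0221; adjusted p = 0.234 with an estimated correlation). The dyskerin gene dkc1 was among them, from 15.7 ± 1.62 to 33.3 ± 3.14. Of 36 genes of the DNA damage response, 11 rose and 8 fell, also adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.748). In it sesn1 fell from 435 ± 72.5 to 221 ± 30.9.

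Immune markers rose together in WT hearts. Of 32 macrophage and monocyte genes, 31 rose, also adjusted over the list alone, with a median of 2.19 (camera adjusted p = 2.86e-21; adjusted p = 0.0244 with an estimated correlation), the only list whose call held in this comparison with an estimated correlation. The cathepsin gene ctsz rose from 36.1 ± 2.32 to 191 ± 23.9 and the amino acid transporter gene slc7a7 from 8.34 ± 0.955 to 62.9 ± 5.80. Of 19 neutrophil genes 14 rose and 2 fell, of 15 genes shared by leukocytes 14 rose, and of 27 cytokine and chemokine genes 17 rose, the same counts adjusted over the list alone. Their medians were 1.2, 1.69 and 0.99 (camera adjusted p = 7.61e-05, 4.37e-11 and 2.4e-06; adjusted p = 0.161, 0.0937 and 0.0937 with an estimated correlation). The NADPH oxidase subunit gene cyba rose from 13.7 ± 2.75 to 53.5 ± 9.09, and the macrophage growth factor gene csf1a from 3.17 ± 0.841 to 18.7 ± 3.57. Of 29 type I interferon response genes 17 rose, also adjusted over the list alone (median 0.49, camera adjusted p = 0.000131; adjusted p = 0.205 with an estimated correlation), including gbp1, from 9.34 ± 1.11 to 48.8 ± 3.84. Of 6 lymphocyte genes 3 rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.286).

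Among structural cell types of WT hearts, 31 of 46 extracellular matrix genes rose and 4 fell (31 and 5 adjusted over the list alone; median 1.09, camera adjusted p = 1.33e-09; adjusted p = 0.0517 with an estimated correlation). The collagen crosslinking gene lox rose from 2.88 ± 0.738 to 24.3 ± 4.10. Of 15 epicardial genes 10 rose and 2 fell, also adjusted over the list alone (median 0.95, camera adjusted p = 0.000161; adjusted p = 0.0937 with an estimated correlation). The retinoic acid synthesis gene aldh1a2 rose from 160 ± 31.4 to 514 ± 67.8. Of 37 genes of cardiomyocyte contraction and calcium handling 26 fell and 4 rose (27 and 4 adjusted over the list alone; median -0.78, camera adjusted p = 4.99e-08; adjusted p = 0.205 with an estimated correlation). The myosin gene myh7ba fell from 665 ± 68.4 to 203 ± 42.8, whereas a gene named myh6 (ENSDARG00000079564) rose from 127 ± 28.0 to 686 ± 46.4. Myosin genes are close copies, so reads could be shared between them. Of 18 red blood cell genes 5 fell (4 adjusted over the list alone; median -0.57, camera adjusted p = 0.0157; adjusted p = 0.55 with an estimated correlation). The endothelial list did not pass (camera adjusted p = 0.182), with 4 of 34 genes higher and 9 lower (4 and 8 adjusted over the list alone). Nor did smooth muscle and bulbus arteriosus (8 of 15 rose and 5 fell, camera adjusted p = 0.192) or skeletal muscle (3 of 11 fell, camera adjusted p = 0.192), the same counts adjusted over the list alone. Of 11 thrombocyte genes 2 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.611).

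Mitochondrial genes fell in WT hearts. Of 70 respiratory chain genes 66 fell and 1 rose, and of 46 genes of fatty acid oxidation and the tricarboxylic acid cycle 42 fell and 1 rose, the same counts adjusted over the list alone. Their medians were -0.89 and -0.91 (camera adjusted p = 2.62e-31 and 2.2e-19; adjusted p = 0.0937 for both with an estimated correlation). The complex I gene ndufs3 fell from 266 ± 11.7 to 122 ± 5.14 and the acyl-CoA dehydrogenase gene acadvl from 2330 ± 264 to 825 ± 127. Glycolysis and hypoxia genes did not pass as a list (5 of 19 rose and 7 fell, camera adjusted p = 0.157). Growth factors and signals studied in heart regeneration did not pass either (14 of 46 rose and 11 fell, camera adjusted p = 0.293), these counts being the same adjusted over the list alone. Of 43 immediate early and stress genes 15 rose and 11 fell (17 and 13 adjusted over the list alone; camera adjusted p = 0.276). Of 9 genes of liver, pancreas, gonad and other nearby organs 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.994), with a median of -0.13 and a mean of 0.31. Cytoplasmic ribosomal protein genes had a median of -0.09, with 2 of 65 higher and 6 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.0263; adjusted p = 0.745 with an estimated correlation). This direction turned to 0.26 (camera adjusted p = 0.0385) with no composition correction. Under that scaling the medians of glycolysis genes, -0.29, and endothelial genes, -0.17, became 0.07 (camera adjusted p = 0.0334) and 0.19 (camera adjusted p = 0.356).

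**Figure D3:**
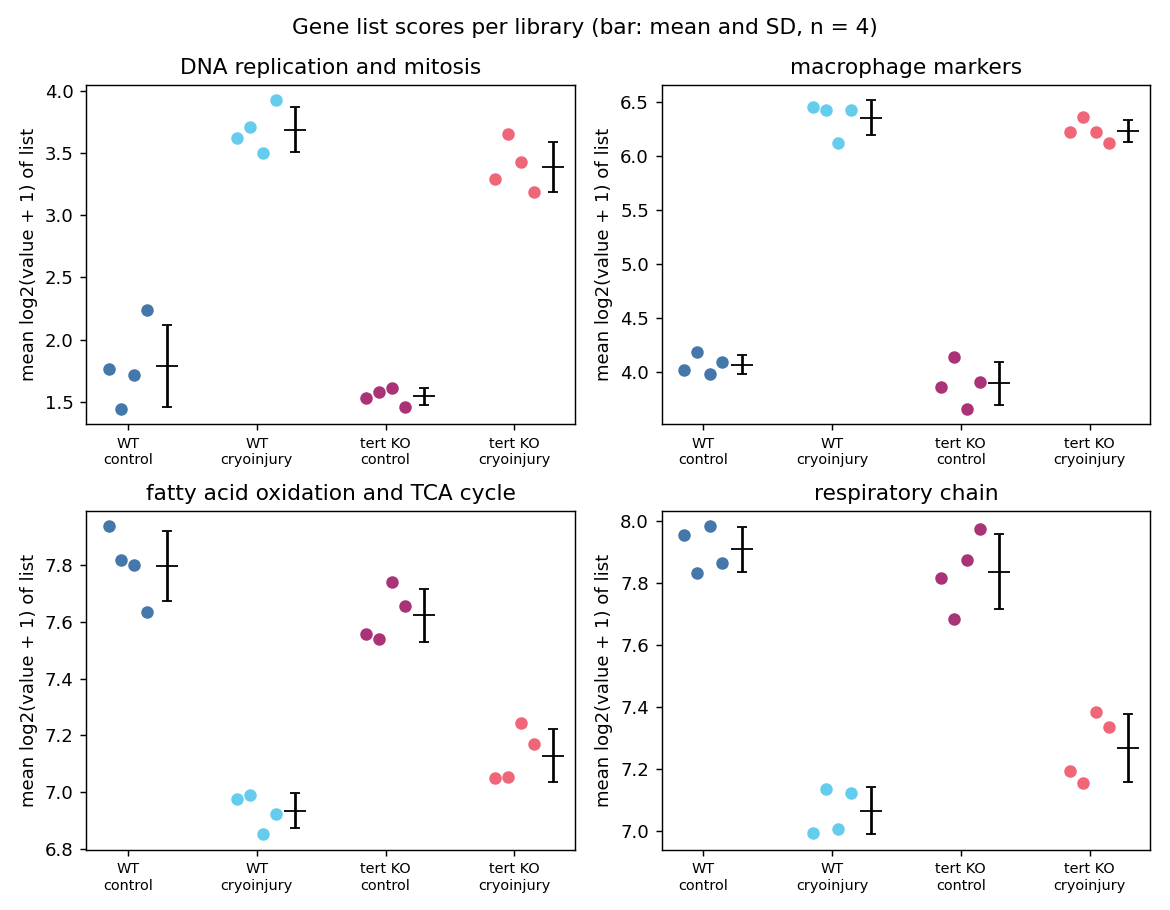
Mean log2(value + 1) of the members of 4 gene lists (vertical axes) in each library of the 4 groups (horizontal axes); points are libraries, and the cross and bar are the mean and SD of 4 libraries. The scores for replication and mitosis and for macrophage markers are higher after cryoinjury in both genotypes, and those for fatty acid oxidation with the tricarboxylic acid cycle and for the respiratory chain are lower.

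In KO hearts, genes raised by cryoinjury included col12a1, fn1 and tnc, and genes lowered by it included irx2 and avpr1a. The col12a1 gene went from 0.671 ± 0.121 to 183 ± 53.7 (SD, n = 4; log2 change 6.74, SE 0.32), and fn1 from 30.2 ± 7.14 to 1350 ± 450 (5.41, SE 0.21). The tenascin C gene tnc, a matrix gene of healing tissue, went from 2.21 ± 1.28 to 92.5 ± 16.2 (4.92, SE 0.30). The gelatinase gene mmp9 was at 1.46 ± 0.784 in KO control, and in KO cryoinjury libraries 1 to 4 it read 106, 442, 21.7 and 39.6 (5.1, SE 0.63), highest in the libraries with the highest krt5. The transcription factor gene irx2 fell from 71.6 ± 7.60 to 17.3 ± 4.83 (-2.02, SE 0.21) and the vasotocin receptor gene avpr1a (ENSDARG00000045788) from 25.6 ± 6.83 to 4.50 ± 0.943 (-2.26, SE 0.23). These 6 genes had limma adjusted p of at most 4.7e-06.

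With limma, 3649 genes were higher and 3253 lower in KO cryoinjury than in KO control, of which 1448 and 267 changed by over 2-fold. The other largest rises were in grna.1 (6.38), grna.2 (5.36), cd9b (5.15), apoeb (5.1), txnb (4.84) and ankrd1 (4.80). The remaining falls by this ranking were in fbxo32 (-1.99), klhl38 (-1.96), gfod2 (-1.85), mpped2 (-1.74), the proline dehydrogenase gene prodha (-1.73), the red cell enzyme gene bpgm (-1.71), gja3 (-1.71) and gpr22 (-1.70). Of 73 replication and mitosis genes 68 rose (71 adjusted over the list alone), with a median of 1.91. Of 32 macrophage genes 31 rose (median 2.16), and of 46 matrix genes 32 rose (median 1.11), the same counts adjusted over the list alone. For these 3 lists camera adjusted p were 1.17e-26, 7.47e-21 and 1.54e-10, and the adjusted p with an estimated correlation were 0.103, 0.0264 and 0.037. Of 19 neutrophil genes 16 rose and 2 fell (median 1.94), of 27 cytokine genes 21 rose (1.18), of 15 leukocyte genes 14 rose (1.79), and of 29 interferon genes 15 rose and 1 fell (0.53), the same counts adjusted over the list alone. Camera adjusted p were 1.08e-06, 2.94e-08, 8.25e-11 and 0.00173, and the adjusted p with an estimated correlation were 0.103, 0.0827, 0.114 and 0.31. The neutrophil list holds mmp9 and the collagenase gene mmp13a, which read 14.2, 212, 10.4 and 4.45 in KO cryoinjury libraries 1 to 4, beside krt5 at 337, 887, 12 and 75.4.

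Of 70 respiratory chain genes 63 fell and 1 rose in KO hearts (median -0.60), and of 37 cardiac muscle genes 26 fell and 5 rose (median -0.64), the same counts adjusted over the list alone. Of 46 fatty acid and tricarboxylic acid cycle genes 36 fell and 1 rose (37 and 1 adjusted over the list alone; median -0.60). In that order camera adjusted p were 1.79e-21, 2.82e-06 and 5.6e-11, and the adjusted p with an estimated correlation were 0.149, 0.29 and 0.149. Epicardial genes also passed (10 of 15 rose and 2 fell; 11 and 2 adjusted over the list alone), as did smooth muscle and bulbus genes (8 of 15 rose and 2 fell; 8 and 3 adjusted over the list alone). So did ribosome assembly (23 of 53 rose and 5 fell) and endothelium (3 of 34 rose and 12 fell), the same counts adjusted over the list alone. In that order camera adjusted p were 0.000112, 0.0343, 0.00447 and 0.0352, and the adjusted p with an estimated correlation were 0.103, 0.149, 0.46 and 0.46. The endothelial call ended without KO cryoinjury libraries 1 and 2 (median -0.04, camera adjusted p = 0.223), and with no composition correction its median was 0.04. The smooth muscle call ended in both settings (camera adjusted p = 0.0653 and 0.0532). The other 11 lists did not pass, and the signs of median, mean and test differed for the DNA damage and skeletal muscle lists. The median change of all genes moved by 0.22, and the lower share of called genes from 47.1% to 22.4%, when no composition correction was made.

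Injury changed largely the same genes in both genotypes. Of the genes called in each, 2903 rose in both, where independent lists would share 882, and 2322 fell in both, where independent lists would share 706. Another 7 were called in opposite directions. Across the 14500 genes, which are not independent replicates, log2 changes correlated with a Pearson r of 0.898 and a Spearman rho of 0.855, and 96.2% of genes called in either had the same sign in both. The comparisons share no library, but they share each gene's estimate of spread from the same fit. Genes with a low spread are thus more easily called in both, and the counts for independent lists are only a rough guide.

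**Figure D4:**
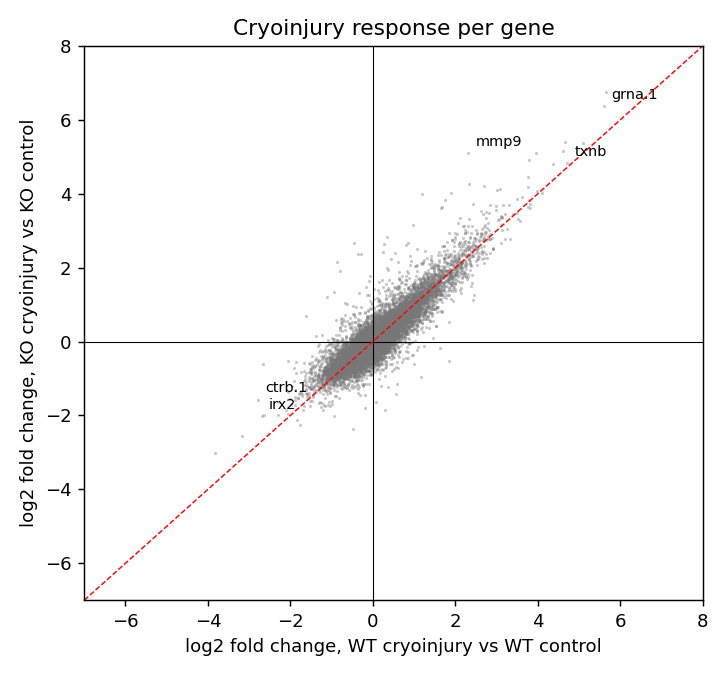
Log2 change after cryoinjury of each of 14500 genes in WT hearts (horizontal axis) and in KO hearts (vertical axis); each point is a gene, and the dashed line marks equal change. Points follow the line (Pearson r = 0.898 across genes), and mmp9 lies above it, at 2.31 in WT and 5.1 in KO.

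No single gene's response to injury differed between the genotypes past the threshold, and lists of mitochondrial genes passed only in camera at its preset correlation. The median difference of the responses was 0.28 for the 70 respiratory chain genes, 68 of them above 0. It was 0.32 for the 46 genes of fatty acid oxidation and the tricarboxylic acid cycle, all above 0. Both lists passed camera (adjusted p = 1.35e-23 and 1.2e-17; adjusted p = 0.605 and 0.41 with an estimated correlation) but not fry (adjusted p = 0.173 and 0.124), and 0 members were called (2 and 7 adjusted over the list alone). For acadvl the response was -1.50 in WT and -0.88 in KO (interaction 0.62, SE 0.17, limma adjusted p = 0.384). When the libraries were the unit, an exact permutation test of the list score (2-sided, 4900 arrangements) gave a difference of 0.37 for fatty acid and tricarboxylic acid cycle genes (p = 0.00286, adjusted over 25 lists 0.0715). The same exact test gave 0.28 for respiratory chain genes (p = 0.018, adjusted 0.225), and neither passed after adjustment. The fatty acid score was 7.80 ± 0.125 in WT control, 7.62 ± 0.093 in KO control, 6.93 ± 0.063 in WT cryoinjury and 7.13 ± 0.094 in KO cryoinjury (SD, n = 4). KO was thus -0.175 from WT in control hearts and 0.195 from it in injured hearts, and both parts enter the difference of 0.37. In KO cryoinjury libraries 1 to 4 this score was 7.05, 7.05, 7.24 and 7.17, beside cardiac muscle scores of 8.83, 8.78, 9.19 and 9.22 and a skeletal muscle score of 5.53 in library 3. The other lists past camera were neutrophil (median difference 0.28), cardiac muscle (0.18), ribosome assembly (-0.09) and cytoplasmic ribosome (0.14), with adjusted p of 0.017, 0.0201, 0.0305 and 5.18e-06, and of 0.846 for each with an estimated correlation. The neutrophil difference includes mmp9 (interaction 2.79, SE 0.89, limma adjusted p = 0.427), which was highest in the KO cryoinjury libraries with the highest krt5. This call ended without KO cryoinjury libraries 1 and 2 (0.08, camera adjusted p = 0.173), as did that of ribosome assembly (-0.06, camera adjusted p = 0.173). With no composition correction the median difference of all genes moved by -0.11, and those of respiratory chain and fatty acid genes were 0.16 and 0.20. Under that scaling neutrophil, cardiac muscle, ribosome assembly and cytoplasmic ribosome genes had 0.16, 0.07, -0.20 and 0.02. The other 19 lists did not pass, and the signs of median, mean and test differed for the DNA damage, macrophage, leukocyte, interferon, regeneration and nearby-organ lists.

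For single genes, limma called 0 interactions, with a smallest adjusted p of 0.112. The insulin receptor substrate gene irs2 (ENSDARG00000075282) was among the genes at that value and was chosen for its interaction after its values were seen. At an unadjusted p under 0.05 limma had 1191 genes, edgeR 1205 and DESeq2 1082, where 725 of 14500 would pass by chance. At the adjusted threshold edgeR called 0 and DESeq2 28. The irs2 gene read 78.5 ± 17.3, 36.0 ± 10.1, 24.8 ± 12.3 and 54.7 ± 10.3 in WT control, WT cryoinjury, KO control and KO cryoinjury (interaction 2.33, SE 0.37).

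Without injury, more genes were lower than higher in KO than in WT hearts. The nuclear receptor gene nr4a3 was at 44.4 ± 32.5 in KO and 257 ± 80.5 in WT (SD, n = 4; log2 difference -2.81, SE 0.52), and the glucocorticoid-induced chaperone gene fkbp5 at 332 ± 261 and 1080 ± 197 (-2.09, SE 0.42). The irs2 gene was at 24.8 ± 12.3 and 78.5 ± 17.3 (-1.72, SE 0.26), and the circadian gene per2 at 21.0 ± 4.88 and 65.0 ± 8.78 (-1.60, SE 0.22). The endothelial, flow-responsive gene klf2a was higher in KO, at 282 ± 46.2 against 143 ± 41.5 (1.01, SE 0.18). So were the glutathione transferase gene gstr, at 424 ± 26.8 against 231 ± 22.0 (0.87, SE 0.11), and fzd7 (ENSDARG00000060004), a Wnt receptor gene, at 24.4 ± 4.59 against 12.9 ± 1.38 (0.86, SE 0.14). These 7 genes had limma adjusted p of at most 0.0185. Of 36 clock genes and 41 glucocorticoid- or fasting-responsive genes, lists drawn up after the values were seen, 7 and 10 passed, and all 10 of the latter were lower.

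With limma, 59 genes were higher and 156 lower in KO control than in WT control, and 6 and 56 of them differed by over 2-fold. The other largest falls were in the pyruvate dehydrogenase kinase gene pdk2 (ENSDARG00000059054, -2.22), the cationic amino acid transporter gene slc7a3 (ENSDARG00000020645, -1.8), midn (-1.65), acta1 (ENSDARG00000036371, -1.52), sptlc2 (ENSDARG00000074287, -1.38) and lmbr1l (-1.34). The other largest rises were in irf2bpl (0.90), rorca (0.84), fzd9 (ENSDARG00000014673, 0.82), tesk2 (0.81), siah1 (0.73), mideasa (0.72) and prickle1 (ENSDARG00000045694, 0.69). With only the 8 control libraries in the fit, limma called 20 higher and 53 lower. Of the genes named so far for this comparison, fkbp5 (adjusted p = 0.0944), pdk2 (0.0636), slc7a3 (0.06), acta1 (0.0613), rorca (0.0688), mideasa (0.101) and prickle1 (0.0682) no longer passed. Single libraries moved the counts to as few as 18 higher and 58 lower without KO control library 2, and as many as 99 and 262 without KO control library 4.

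Among the lists, 72 of 73 replication and mitosis genes did not pass in this comparison, also adjusted over the list alone. The replication helicase gene mcm6 was lower, at 3.10 ± 0.27 in KO and 8.17 ± 3.39 in WT. The list's median was -0.24, with 62 members below 0 (camera adjusted p = 0.000302). Extracellular matrix had a median of -0.24 (camera adjusted p = 0.00233), and its 2 called members were lower (2 higher and 6 lower adjusted over the list alone). These were the elastin gene elnb, at 44.8 ± 15.9 against 91.7 ± 14.5, and loxl2a, at 4.10 ± 1.91 against 12.8 ± 5.68. Interferon genes had a median of 0.24 (camera adjusted p = 0.00732), and their only called member was lower, the class I histocompatibility gene mhc1uba (5 higher and 1 lower adjusted over the list alone). Macrophage markers had a median of -0.17 (0 called, 1 lower adjusted over the list alone; camera adjusted p = 0.0295). Fatty acid and tricarboxylic acid cycle genes had a median of -0.06 (4 lower, 5 adjusted over the list alone; camera adjusted p = 0.029), with the uncoupling protein gene ucp2 at 104 ± 13.9 against 198 ± 30.1. Respiratory chain genes had a median of -0.05 (1 lower, 2 adjusted over the list alone; camera adjusted p = 0.0484). The adjusted p with an estimated correlation was 0.919 for each of these 6 lists. With no composition correction the lower share of called genes was 61.3% instead of 72.6%, and the last 2 list calls ended (medians -0.01 and 0.00, camera adjusted p = 0.0924 and 0.333). The other 19 lists did not pass. Called members of those included klf2a, dll4 and gata5 of the endothelium (3 higher, also adjusted over the list alone) and the epicardial gene tcf21 (0.63). The apoptosis gene bbc3 (-1.34) of the DNA damage list was called too (1 lower, 2 adjusted over the list alone), as were egr1 (1.8), atf3 (-1.07) and xbp1 (-0.49) of the stress list (3 higher and 2 lower; 5 and 8 adjusted over the list alone). With only the 8 control libraries in the fit, mcm6, loxl2a, bbc3, dll4, gata5, egr1, atf3 and xbp1 did not pass (limma adjusted p = 0.0512 for gata5 to 0.122 for xbp1). For 4 lists that did not pass, the signs of median, mean and test differed: telomere, cytokines, endothelium and regeneration signals.

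After cryoinjury, genes higher in KO than in WT hearts included tbx5, acadvl, gpr22 and avpr1a, and those lower included mhc1uba and mhc1uca. The transcription factor gene tbx5 was at 31.4 ± 5.44 in KO and 17.8 ± 1.77 in WT (SD, n = 4; log2 difference 0.77, SE 0.12), and acadvl at 1290 ± 152 and 825 ± 127 (0.65, SE 0.12). The receptor gene gpr22 was at 133 ± 21.1 and 80 ± 10.6 (0.72, SE 0.11) and a second vasotocin receptor gene avpr1a (ENSDARG00000077083) at 26.6 ± 1.22 and 14.9 ± 0.896 (0.79, SE 0.10). The class I histocompatibility genes mhc1uba and mhc1uca were lower in KO, at 11.6 ± 5.71 against 37.0 ± 4.96 (-1.67, SE 0.22) and at 11.5 ± 2.97 against 21.8 ± 3.5 (-0.89, SE 0.16). These 6 genes had limma adjusted p of at most 0.0272. Without injury gpr22 and tbx5 were higher in KO too, with no overlap of libraries, though not past the threshold. There gpr22 read 403.7 to 451.88 in KO and 293.48 to 335.55 in WT, and tbx5 86.29 to 94.72 and 56.47 to 78.51. The control libraries of the genotypes overlapped for acadvl and this avpr1a, and mhc1uba was lower in KO there too. Without KO cryoinjury libraries 1 and 2, tbx5 (adjusted p = 0.0803), acadvl (0.0729), gpr22 (0.0783), mhc1uba (0.0608) and mhc1uca (0.0733) did not pass. That fit held fewer libraries, and in that order the differences were 0.67, 0.75, 0.6, -1.36 and -1.01. With only the 8 injured libraries in the fit, tbx5 (0.0575), acadvl (0.0834), gpr22 (0.0679) and mhc1uca (0.0999) did not. Class I genes are close copies that vary between fish, so reads could be shared among them or miss the reference.

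With limma, 42 genes were higher and 22 lower in KO cryoinjury than in WT cryoinjury, of which 9 and 8 differed by over 2-fold. The other genes named as higher were the keratin gene krt91 (1.31), sult2st1 (1.19), sync (0.76), gstr (0.68), the endothelin receptor gene ednrab (0.68) and fam222b (ENSDARG00000059886, 0.66). Those named as lower were per2 (-1.04), dennd4a (-0.71), the scavenger receptor gene stab1 (-0.65), sat1 (ENSDARG00000035652, -0.61), osgn1 (-0.53), s100u (-0.52) and ptpn11b (-0.40). Beside krt5, krt91 read 134, 291, 122 and 124 in KO cryoinjury libraries 1 to 4 and 63.2 ± 12.8 in WT cryoinjury. The antigen processing genes tap2a and psmb13a were also called higher (2.27 and 2.52, limma adjusted p = 0.0238 and 0.0375). For tap2a there were 31, 0, 14 and 0 reads in WT cryoinjury libraries and 68, 95, 33 and 40 in KO cryoinjury libraries, again with the most in libraries 1 and 2. Control hearts held 2, 3, 3 and 0 tap2a reads in WT and 20, 28, 14 and 11 in KO. For psmb13a they held 4, 17, 8 and 0 in WT and 36, 25, 18 and 15 in KO. Both were thus higher in KO without injury too, though not past the threshold (1.54 and 1.3, limma adjusted p = 0.0698 and 0.216). Without KO cryoinjury libraries 1 and 2 limma called 4 genes higher and 1 lower. They included gstr (0.81, adjusted p = 0.0107) and avpr1a (ENSDARG00000077083, 0.82, adjusted p = 0.0318), and the other genes named here as higher or lower did not pass (adjusted p = 0.0583 for krt91 to 0.247 for psmb13a). That fit held fewer libraries, and these genes kept their direction in it. The difference was 0.83 for sync, 1.53 for sult2st1 and -0.68 for dennd4a. It was smaller than with all libraries for per2 (-0.6), krt91 (0.97), tap2a (1.71) and psmb13a (2.02). With only the 8 injured libraries in the fit limma called 11 and 14, and krt91, sult2st1, gstr, tap2a, psmb13a, per2, stab1, osgn1 and ptpn11b did not pass (adjusted p = 0.064 for gstr to 0.125 for per2). Leaving out single libraries gave 10 higher without WT cryoinjury library 2 and 5 lower without WT cryoinjury library 3, and at most 51 higher without KO cryoinjury library 3 and 40 lower without KO control library 4. With no composition correction the lower share of called genes was 62% instead of 34.4%.

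Among the lists, those of mitochondrial genes had medians above 0 in injured KO against injured WT hearts and passed only in camera at its preset correlation. The median was 0.21 for the 70 respiratory chain genes, 66 of them above 0, and also for the 46 genes of fatty acid oxidation and the tricarboxylic acid cycle, 40 of them above 0. Both passed camera (adjusted p = 4.5e-22 and 5.14e-12; adjusted p = 0.57 for both with an estimated correlation) but not fry (adjusted p = 0.118 for both). An exact permutation test of each list score (2-sided, 70 arrangements) gave an adjusted p of 0.238 for both, with the smallest unadjusted p it can give, 0.0286. Of these, sdhb passed in the first and acadvl and acadm in the second, and 30 and 19 passed adjusted over the list alone. The calls of sdhb and acadm ended without KO cryoinjury libraries 1 and 2 (limma adjusted p = 0.0608 and 0.0583), a fit with fewer libraries. The differences there, 0.53 and 0.6, were as large as in any setting. Both calls also ended with only the 8 injured libraries (limma adjusted p = 0.126 and 0.0959). Replication and mitosis genes had a median of -0.31, with 67 of 73 members below 0 and 0 called over all genes or adjusted over the list alone. The list passed camera (adjusted p = 2.03e-10; adjusted p = 0.57 with an estimated correlation) but not fry (adjusted p = 0.344) or the exact test of its score (p = 0.0857, adjusted p = 0.428). In it ccnb1 was at 13 ± 2.98 in KO and 18.3 ± 2.38 in WT. Ribosome assembly (median -0.14), macrophage (-0.17) and cytoplasmic ribosome genes (0.09) also passed camera but not fry (adjusted p = 0.158, 0.4 and 0.56), with 0 called members in each, also adjusted over the list alone (camera adjusted p = 7.88e-07, 0.00483 and 1.97e-05; adjusted p = 0.57, 0.57 and 0.674 with an estimated correlation). The other 19 lists did not pass, and the signs of median, mean and test differed for lymphocyte and glycolysis genes.

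The genotype differences in control and in injured hearts had 4 higher and 7 lower genes in common, where independent lists would share 0.171 and 0.237. Here too each gene's estimate of spread was shared, so the lists are not fully independent. The genes in common are named next. Apart from tert the genes in common included gstr, fam222b and pdcd4, higher in KO, and per2, mhc1uba, s100u and the granulin-like gene grnas, lower in KO. Of these, pdcd4 and grnas were chosen after their values were seen. In the gene order of the assembly GRCz12tu, gstr, mhc1uba, s100u, grnas, krt91, sync, tap2a and psmb13a lie on the chromosome of tert, where 12 of 362 genes were called in either genotype comparison, against 139 of 8682 on other chromosomes. Across all genes, which are not independent replicates, log2 differences in control and injured hearts, which share no library, correlated with a Pearson r of 0.316 and a Spearman rho of 0.277.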

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

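Tests of the explanations weighed here were chosen after the results were seen, whereas the gap test on library values and the test of the interaction were set before the data were examined. In each group of 4 libraries, a value was taken up when its gap to the nearest other library was a larger part of the group's range than chance allows in 95% of groups (Dixon's test). This held for 40 of 580 groups, where chance alone gives about 29, so a single one of these values says little. Values are in deposited units, with the other 3 libraries of the group after each.

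In WT control, library 1 was apart for pygl (20.69, others 40.03 to 42.04), acadvl (2717.38, others 2141.61 to 2228.22) and sptlc2 (163.58, others 105.03 to 111.09). Library 2 was apart for myh6 (169.08, others 111.06 to 117.16), pdk4 (83.55, others 102.12 to 105.58) and lepb (0.13, which is 1 read, others 0). Library 3 was apart for irx2 (65.51, others 33.29 to 37.84), mtus1a (171.7, others 110.69 to 119.55) and gfod2 (62.68, others 44.03 to 45.79). Library 4 was apart for pgam2 (385.46, others 373.67 to 374.42), tap2a (0, others 0.35 to 0.4, which is 2 to 3 reads) and the thrombocyte score (4.04, others 3.77 to 3.81 on the log2 scale).

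In WT cryoinjury, library 1 was apart for aplnrb (9.62, others 15.32 to 16.37), stab1 (206.76, others 145.95 to 154.86) and mmp13a (9.26, others 2.45 to 3.6). Library 3 was apart for sesn1 (267.6, others 204.58 to 208.28), lepb (3.14, others 5.63 to 5.82), slc7a3 (104.78, others 43.04 to 47.49) and the macrophage score (6.12, others 6.43 to 6.46). Library 4, the deepest, was apart for txnb (130.46, others 98.5 to 100.04) and sdhb (197.07, others 162.33 to 166.34).

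In KO control, library 1 was apart for dkc1 (9.61, others 13.06 to 13.72), itgb2 (60.49, others 52.6 to 53.72), acadvl (2018.48, others 2437.82 to 2502.97) and gapdh (12544.85, others 14067.28 to 14350.62). Library 2 was apart for mideasa (27.73, others 21.96 to 22.67). Library 3 was apart for tnc (4.12, others 1.35 to 1.76), mcm6 (3.51, others 2.94 to 3), elnb (68.45, others 35.14 to 39.61), lepb (0.15, which is 1 read, others 0) and the epicardium score (6.12, others 5.94 to 5.95). Library 4 was apart for grna.1 (6.08, others 0.76 to 1.35) and sdhb (343.9, others 310.27 to 313.7).

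In KO cryoinjury, library 1 was apart for cd9b (230.73, others 37.72 to 70.25), and library 2 for krt91 (291.27, others 122 to 133.89) and mmp13a (211.77, others 4.45 to 14.18). Library 3 was apart for tcf21 (43.23, others 33.41 to 34.26) and the skeletal muscle score (5.53, others 3.91 to 4.13). Library 4 was apart for mhc1uba (20.16, others 8.39 to 9.18) and for its reads, 8.81 against 5.61 to 6.11 in units of 1e6.

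By camera on the interaction, 6 lists passed the threshold at its preset correlation. The median differences were 0.28 for neutrophil, 0.18 for cardiac muscle, 0.28 for respiratory chain, 0.32 for fatty acid and tricarboxylic acid cycle, -0.09 for ribosome assembly and 0.14 for cytoplasmic ribosome genes. No call held with an estimated correlation or in fry.

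Epithelial genes were high in KO cryoinjury libraries 1 and 2, where krt5 read 337 and 887, epcam 10.06 and 45.82 and cldnb 12.66 and 92.95, against 12 and 75.4, 0.17 and 3.9, and 1 and 5.68 in libraries 3 and 4. A larger injured share of the heart stays open, since neither sign set for it was met. The sign for it was a median change of the skin genes in WT injury at or above their rise in these libraries. The sign against it was a median change in WT injury at or below 0, with none called higher. The 28 skin genes as a set rose more in these libraries than in WT injury. Their median rise in these libraries over KO control was 1.8, but their median change in WT injury was 0.03 (SD over genes 0.71). An injury score, the mean log2 value of 200 other genes raised in WT injury, was 6.07 and 6.26 in these libraries. Its genes were chosen by their rise in the WT libraries, which can favour the WT cryoinjury values. It was 6.09 and 5.94 in libraries 3 and 4, and 6.18 to 6.32 in WT cryoinjury. Cardiac muscle scores were lower in KO cryoinjury libraries 1 and 2, at 8.83 and 8.78 against 9.19 and 9.22 in libraries 3 and 4. Of the 28 skin genes 5, krt4 among them, were called higher in WT injury and 1 lower. Skin tissue in these libraries may account for the pattern, and this stays open. Over 17 skin genes outside the 500 most variable genes, the median log2 value was 5.09 and 5.34 in the 2 libraries. That was only 0.19 above the highest of the other 14, where over 1 had been set as the sign of skin. Leaving out the most variable genes removed the skin genes that rose most here, so missing the sign does not weigh against skin. Of the 28 genes 23 were above 1 unit in control hearts and 3 were in other lists, and of the most abundant, krt94 read 1695.31 and 2031.97 in these 2 libraries and 1487.61 to 2051.48 in the others, whereas krt4 read 677.54 and 784.19, against 523.28 to 765.34 in the other cryoinjury libraries and 163.04 to 282.39 in controls. The labels do not part these libraries from the other 2 of their group, so no other biological explanation was tested.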

How the results depend on the processing

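All alternatives were set before the data were examined except edgeR on recovered reads and the fit without KO cryoinjury libraries 1 and 2. The cause of a change was not tested unless named. Results were counted whether or not they were called in the main fit, so those that kept their side include results called in neither fit. Of gene results under settings other than leaving out a library, 2314 kept their side of the threshold, 95 lost a call, 5 gained one and 1 reversed. Of list results 883 kept their side, 74 lost a call, 42 gained one and 1 reversed. With no composition correction, 6519 genes were higher and 1227 lower in WT injury, 1540 lower in KO injury, 62 lower in injured KO than WT hearts, and 11 lists passed for the interaction. The WT injury change of gata5 reversed to 0.06, and that of cytoplasmic ribosome genes to 0.26, where the median change of all genes moved by 0.33. The DESeq2 Wald test called 136 higher and 285 lower between genotypes in control hearts, 138 and 84 in injured hearts, and 25 and 3 for the interaction. With the 8 compared libraries alone it was 20 and 53 in control hearts, 11 and 14 in injured hearts, and tert in injured hearts was 0.9 (adjusted p = 0.115), with fewer residual degrees of freedom. Voom called 102 lower in control hearts, and a pseudocount of 10 gave 25 higher in injured hearts. Without KO cryoinjury libraries 1 and 2, 4 genes were higher and 1 lower in injured hearts, 10 lists passed there, and tert was 0.91 (adjusted p = 0.169), with fewer libraries. By edgeR tert was 0.99 (adjusted p = 0.0529). With an estimated correlation 1 list passed in WT injury, 2 in KO injury and 0 in the other contrasts, and fry gave 0 in both genotype contrasts and the interaction. At an adjusted p under 0.01, a stricter threshold, 1541 genes fell in both injury responses and 1 was called in opposite directions.

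The replicate block gave 36 lower in injured hearts and 1 higher for the interaction, ended the injured-heart call of ptpn11b (-0.4, adjusted p = 0.058), and kept other counts within 1.5 times. The replicate numbers were not taken to pair the libraries, since of 24 same-numbered pairs only 4 had a correlation over 0.1 (from -0.05 to 0.19). As a hint that leaves pairing open, 8 of 16 libraries correlated best with their own number, where 4 would by chance.

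Leaving out each library gave 18 (without KO control 2) to 99 (KO control 4) higher and 58 (KO control 2) to 262 (KO control 4) lower in control hearts. In injured hearts it gave 10 (WT cryoinjury 2) to 51 (KO cryoinjury 3) higher and 5 (WT cryoinjury 3) to 40 (KO control 4) lower, with tert from 0.75 (WT cryoinjury 1) to 1.1 (WT cryoinjury 4). The interaction had 0 to 3 higher (WT control 2). Lists past the threshold ranged from 3 (KO control 1) to 7 (WT control 1) in control hearts, 6 to 10 (KO cryoinjury 3) in injured hearts and 4 (WT cryoinjury 4) to 10 (WT cryoinjury 2) for the interaction, and opposite calls from 4 (WT cryoinjury 2) to 10 (WT control 2). Injury counts moved less, from 3189 to 3526 higher and 2801 to 3158 lower in WT, and 3316 to 3692 and 2799 to 3303 in KO. Testing with no filter was not run as a separate setting, because low genes had been left out before deposit. Thinning every library to 5611576 reads, the smallest total, kept all counts within 1.5 times.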

Other observations

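Tests of explanations here, and the clock, glucocorticoid and skin lists, were chosen after the results were seen, except that the test on uncalled genes of the chromosome of tert was set before its own value was seen. The counts over other splits of the libraries were set before the data were examined. Several other genes passed in the injury comparison of both genotypes. The leptin gene lepb, a gene with a known injury-responsive enhancer in zebrafish, was at 0.0329 ± 0.0659 in WT control and 5.06 ± 1.28 in WT cryoinjury, and at 0.0381 ± 0.0762 and 5.49 ± 2.71 in KO (SD, n = 4; limma adjusted p = 1.28e-06 and 1.52e-06). The proglucagon gene gcga, known from the pancreas, rose from 2.04 ± 1.11 to 32.5 ± 10.1 in WT and from 1.86 ± 1.1 to 30.9 ± 13.3 in KO (adjusted p = 2.23e-07 and 2.58e-07). The chaperone gene clu rose from 14.4 ± 1.57 to 82.2 ± 8.46 in WT and from 11.9 ± 2.02 to 79.4 ± 7.97 in KO, and the hyaluronan-binding gene tnfaip6 from 10.6 ± 0.748 to 75 ± 13.9 and from 10 ± 2.83 to 75.4 ± 26. The antiviral gene mxa rose from 2.04 ± 0.211 to 12 ± 3.49 in WT and from 2.17 ± 0.746 to 13.3 ± 3.4 in KO.

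Among genes that fell in both, the pyruvate dehydrogenase kinase gene pdk4 fell from 98.8 ± 10.3 to 35.8 ± 6.59 in WT (log2 change -1.45, SE 0.12), and its log2 change in KO was -1.03 (SE 0.12). The fixed list of glycolysis and hypoxia genes did not pass camera in either genotype, with 4 of 19 higher and 10 lower in KO (also adjusted over the list alone; camera adjusted p = 0.144). The glycolysis regulator gene pfkfb4a fell from 38.8 ± 2.92 to 13.9 ± 1.69 in WT and from 32.4 ± 4.51 to 19.1 ± 2.41 in KO. For pdk4 and pfkfb4a the differences between genotypes, 0.43 (SE 0.17) and 0.70 (SE 0.16), did not pass (limma adjusted p = 0.559 and 0.384). The muscle glycolysis gene pgam2 fell from 377 ± 5.68 to 197 ± 15 in WT and from 368 ± 30.2 to 225 ± 22.8 in KO. The endothelial apelin receptor gene aplnrb fell from 31.8 ± 5.94 to 14.4 ± 3.2 in WT and from 42.2 ± 3.72 to 19.3 ± 3.37 in KO.

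Other splits of the libraries were counted for each comparison, with only its 8 libraries in the fit. Of the 35 splits, 1 gave as many genes in each pairwise comparison, the real split itself. The real counts were 6698, 6304, 73 and 25 for WT injury, KO injury, genotype in control hearts and genotype in injured hearts, and the highest other split gave 0, 2, 2 and 4. With 35 splits the real one can rank at best 1 of 35. Mixed splits also add a real group difference to their spread, which lowers their counts. The counts thus set the real split apart but cannot exclude chance. For the interaction the real count was 0, so all 100 draws had to give as many and the count says nothing about chance. The draws had a median of 0, a second highest count of 9 and a highest of 113. The draw with 113 parted the control libraries by genotype, and the injured ones too but for WT library 1 and KO library 3, with the sides exchanged in control hearts, so that it summed the genotype differences of control and injured hearts.

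For the genes lower in KO control than in WT control hearts, scaling between libraries was argued against, since 117 genes were lower without the composition correction and 156 with it. A difference in time of day or light at sampling could account for clock genes among them, and it stays open: of 36 clock genes 14 had an unadjusted p under 0.05 (Fisher's exact odds ratio 3.39, 95% interval 1.6 to 6.94, 2-sided p = 0.000724), but without the 7 past the threshold the odds ratio was 1.87 (0.672 to 4.53, p = 0.18). Glucocorticoid or feeding state stays open too: 10 of 41 responsive genes were lower past the threshold and 0 higher, with a median of -0.31. The other 31 had a median of -0.13 (limma's camera, unadjusted p = 0.0835). The 10 past the threshold were left out of that median, so it does not weigh against the explanation either. Neither explanation can be told apart from an effect of the tert genotype itself, because the labels give no sampling time or feeding and each genotype has a single set of control libraries.

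Genes called in either genotype comparison lay more often on the chromosome of tert, where 12 of 362 genes were called (tert left out), against 139 of 8682 on other chromosomes (Fisher's exact odds ratio 2.11, 95% interval 1.05 to 3.85, 2-sided p = 0.0199; 9044 genes with a chromosome in assembly GRCz12tu). This test takes genes as independent, so its p may be too small. In WT cryoinjury libraries 1 to 4, tap2a read 3.64, 0, 1.37 and 0, and psmb13a moved with it, at 7.04, 0, 1.37 and 0.18. The 12 called genes were psmb13a, tent5bb, sync, tap2a, krt91, gpd1c, gstr, rnf19b, s100u, mhc1uba, si:ch211-264f5.2 and grnas. Of these, psmb13a, sync, tap2a and krt91 were called in injured but not in control hearts. Without KO cryoinjury libraries 1 and 2, a fit with fewer libraries, they did not pass (2.02, 0.83, 1.71 and 0.97). A candidate explanation, variants carried with the tert allele, stays open. Over 350 genes on the chromosome of tert called in neither comparison, genotype differences in control and injured hearts had a Spearman rho of 0.351. These genes are not independent replicates. On 24 other chromosomes the median was 0.248 (SD 0.064, highest 0.415), and 3 of them were higher, where above all others had been set as the sign. The called genes that made the pattern were left out of this test. Missing the sign thus does not weigh against linked variants. The antigen processing gene psmb8, chosen after its values were seen and of a region known to differ between fish haplotypes, read 13.13, 0.19, 4.32 and 0.18 in WT cryoinjury libraries 1 to 4, and 30.8, 33.97, 13.35 and 10.36 in KO cryoinjury. An effect of the tert genotype itself on these genes was not tested apart from linkage.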
